A study of Mus musculus with 51 samples.

How the data were processed

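RNA from clonal mouse stromal lines was hybridised to Affymetrix mouse gene 1.0 ST arrays, per the labels' protocols, from 100 ng of total RNA extracted with Trizol and labelled with biotin. The 51 arrays formed 17 groups of 3. Of these, 39 arrays came from confluent cultures of 13 lines, and 12 came from 2 fetal liver lines that had been grown with or without hematopoietic cells and purified after 4 days by absence of the leukocyte antigen CD45, per the labels' protocols. The deposited values were log2 signals per probe set. The authors made them with RMA and Partek, per the submitters' processing notes; versions, settings and the order of the steps were not given in the sources used here. The values held no negative and no missing entries. Their quantiles matched within 4 separate sets of 18, 6, 12 and 15 arrays and differed between sets, so the arrays had been normalized in 4 parts, and levels are comparable only within a part. The array medians lay between 5.04 and 7.14 on the log2 scale over the 4 sets, and no 2 arrays held identical values.

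The deposited table held 35556 probe sets, of which 21789 were paired with 1 gene symbol, 1621 with several and 12146 with none. Probe sets naming 1 symbol were used, and for the 998 genes with several such probe sets the one with the highest mean over all 51 arrays was taken, which left 19938 genes. For 19856 of these genes the Entrez identifier was found in the RefSeq gene table, and 0 symbols differed. No filter on low signal was applied. Differences were tested with limma 3.58.1 in R 4.3.3 (linear model, contrasts, moderated statistics by empirical Bayes), with two-sided p-values adjusted by Benjamini and Hochberg over all genes tested and a threshold of 0.05. Files were read with the R package data.table (version 1.17.8), statmod 1.5.0 was used for the random block, and plots were drawn with matplotlib 3.10.9 in Python 3.11.15. The number of arrays, 3 per group, limits the precision.

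The groups, tests, gene lists, rule for named genes and alternatives were chosen before the data were examined, except where a test or an alternative is said to have been chosen later. The confluent pairs were contrasts of 1 fit to all 39 confluent arrays with a mean per line, each pair lying within 1 normalization set. The contrasts of sorted stroma were taken from 1 fit to the 12 sorted arrays. Standard errors of these contrasts come from the spread pooled over all arrays of a fit and can differ from the SDs of the groups compared. For support and for tissue across lines, the unit was the line: the means of 12 lines from the aorta-gonad-mesonephros region (AGM), fetal liver (FL) and bone marrow (BM) were fitted with terms for support, tissue and normalization set. The set term was added after the separate normalization was seen, since a test across sets without it would read differences in scale as biology; it leaves the line BFC, which was alone in its set among these lines, without weight. The fit without this term is given as an alternative. OP9 was left out of the tests across lines because it was the only line of its tissue.

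For each of the 4 confluent pairs, the sorted pair and each contrast with hematopoietic cells, the named genes were the 8 with the largest positive and the 8 with the largest negative difference among those past the threshold, with every array of one group above every array of the other. Left out of this choice were symbols of Gm and digits, those ending in Rik, LOC symbols, accession-like symbols of BC, AK or AI, and the Mir, Snora, Snord, n-R5s, Olfr and Vmn genes. Other clone-like symbols (AW, AU or DQ) stayed in. For genes shared by 3 pairs the 10 with the largest smallest difference per direction were named, for tests across lines with fewer than 4 genes passing the 6 smallest p-values, and up to 4 members of each described list, with the largest differences. Where any other gene is named, it was chosen after its values were seen. A set of 41 gene lists, holding 1148 distinct genes of which 1075 were measured, was tested per contrast with limma's camera at a preset correlation of 0.01 between genes and again with an estimated correlation, adjusted over the lists of a contrast; the counts of members past the threshold were taken over all genes and, again, adjusted over the list alone. The fry test of limma was a further alternative.

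Replicate numbers in the labels were checked for pairing by correlating, across genes, the deviations of same-numbered arrays from their group means; a pair of groups was called paired where each of the 3 correlations was above 0.1. This held in the data for the AGM pair (0.535, 0.327 and 0.468), the BM pair (0.323, 0.116 and 0.435) and the FL pair of sorted cells grown alone (0.671, 0.517 and 0.466). It held for none of the other pairs of groups checked, and OP9 with BFC was not checked. The highest correlation between different numbers was 0.103 in the AGM pair. It was 0.194 in the BM pair and 0.501 in the sorted pair, above the lowest of equal numbers, so the pairing in these 2 rests on less. Deviations from a mean of 3 arrays sum to 0, so the 3 correlations are not separate evidence. In the sorted pair replicate 1 stood apart in both lines, which alone makes replicates 2 and 3 correlate, whatever their number. A pairing beyond replicate 1 was not shown there. Alternatives tried were the replicate number as a block, only the arrays of a pair or of a set, cyclic loess, removal of the 30% dimmest genes, the mean of a gene's probe sets, all probe sets, a trended and robust variance, a 2-fold minimum, other thresholds, other covariates, and leaving out each array or line in turn. The limma fits and the camera test at the preset correlation were first tested on simulated data built on the real means and spreads, with seeded changes. The fry test, the count of shared genes and the check for pairing were not simulated. At a log2 change of 1, 98.5% of the changed genes were recovered in the AGM pair, 97.0% in the FL and BM pairs and 80.6% in the sorted pair. The share was 65.7% in the interaction, 68.7% for support across lines and 70.1% for tissue. The simulated noise was independent between genes and arrays, while in the real sorted arrays replicate 1 deviated alike in both lines. In the real test for support Gpr39 (-2.15 ± 0.255, SE) did not pass. Recovery in the real data may therefore be lower, and a count of 0 does not show absence.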

Results

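Expression was measured in 17 groups of 3 arrays each. The confluent cultures comprised 13 stromal lines, labelled by whether they support hematopoietic stem and progenitor cells (HSPCs) in culture. From the AGM, the embryonic site where hematopoietic stem cells emerge, came UG26.1B6, AM14-1C4 and AM30-3F4 (supportive) and UG26.3B5 (less supportive), from embryonic day 11. From FL at embryonic day 14.5 came AFT024 and 2012 (supportive) and BFC012, BFC and AFT011 (non-supportive). The label of BFC gives no clone number, and it was taken as a line of its own, not as BFC012. From adult BM came BMC9 and 14F1-1 (supportive) and BMC10 (less supportive), and from fetal calvaria the supportive line OP9. The remaining 12 arrays held AFT024 and BFC012 stroma sorted after 4 days of culture with or without bone marrow c-Kit+Sca1+Lin- cells (KLS cells), a fraction enriched for HSPCs. Within groups the lowest correlation between arrays was 0.991, 0.994, 0.972 and 0.994 in the 4 normalization sets, the 0.972 among the sorted cells. The labels do not say that replicates were separate cultures, so p-values measure only the spread between these arrays, which may be technical. Differences are log2 values, supportive minus less or non-supportive line, or with minus without KLS cells, and limma gave the tests.

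The AGM pair asked what separates a supportive from a less supportive line of the same tissue and strain. UG26.1B6 carried less of the imprinted noncoding RNA Meg3, which averaged 6.72 ± 0.085 (SD, n = 3) against 10.25 ± 0.296 (SD, n = 3) in UG26.3B5, a difference of -3.53. DQ267102 (-2.90) was lower too, as were the membrane glycoprotein Gpnmb (-3.45), Tmem47 (-2.92), AU018091 (-2.91), thrombomodulin Thbd (-2.85), the oxidized lipoprotein receptor Olr1 (-2.40) and the zinc-sensing receptor Gpr39 (-2.34). Higher in UG26.1B6 were AW551984 (3.28), the transcription factor Tbx20 (2.96; 8.52 ± 0.621 against 5.56 ± 0.154, SD, n = 3 each), cyclin D2 (Ccnd2, 2.90), the protein kinase A regulatory subunit Prkar1b (2.62), Akip1 (2.5), Nudt14 (2.37), the fatty acid binding protein Fabp7 (2.36) and the ephrin Efna5 (2.33). Standard errors of these 16 differences lay between 0.11 and 0.33. In all, 1707 of 19938 genes passed, 865 higher and 842 lower in UG26.1B6, and 201 of them differed at least 2-fold.

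Cholesterol and fatty acid synthesis was the list with the smallest camera p in the AGM pair: of 29 measured genes 12 were higher in UG26.1B6, 0 lower and 17 did not pass (18 and 0 adjusted over the list alone; camera adjusted p = 2.6e-09, adjusted p = 0.531 with an estimated correlation). Its largest members were Hmgcs1 (1.06), Idi1 (1.05), Cyp51 (0.75) and Pmvk (0.70), enzymes of the sterol pathway. Among 57 Wnt pathway genes 10 were higher, 2 were lower and 45 did not pass (12 and 3 adjusted over the list alone; camera adjusted p = 0.0111, adjusted p = 0.531 with an estimated correlation). The receptors Fzd6 (2.02) and Ror2 (1.89) and the secreted Rspo3 (1.27) and Sfrp2 (1.03) were the largest. The 39 measured HSC niche factors, secreted or surface proteins reported to act on stem cells, held 6 higher, 3 lower and 30 that did not pass (10 and 3 adjusted over the list alone). Camera did not separate them from other genes (adjusted p = 0.204, adjusted p = 0.711 with an estimated correlation). The matrix proteins Tnc (1.8) and Postn (1.66) and the matrix inhibitor of calcification Mgp (1.39) were higher, and Prg4 (-1.33) was lower. For the imprinted growth genes 5 of 18 were higher, 3 lower and 10 did not pass (7 and 4 adjusted over the list alone). This list had a median of 0.06, a mean of -0.09 and a camera adjusted p = 0.973 with direction down (adjusted p = 0.995 with an estimated correlation). Camera called 10 of the 41 lists with the preset correlation and 0 with an estimated one. With only the 6 arrays of this pair the count of genes was 748, or 2217 with the replicate number as a block (chosen after seeing the data), with the 18 arrays normalized together 828, and without replicate 2 of UG26.1B6 1122.

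The Meg3 difference belonged to a run of transcripts on mouse chromosome 12, looked at after the values were seen. Of 44 measured transcripts from Meg3 up to Dio3, Meg3 included and most of them microRNAs, 43 were lower in UG26.1B6 and 39 of these passed, with a median difference of -0.83. Rian was at -1.50 and Mir377 at -3.06. The neighbouring gene Dlk1 did not pass (0.33, adjusted p = 0.106), nor did Dio3 (0.07, adjusted p = 0.842), while Rtl1 was lower (-0.31, adjusted p = 0.0446). The same 44 transcripts had medians of -0.03 in the FL pair, -0.006 in the BM pair and 0.11 in the second FL pair.

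**Figure D1:**
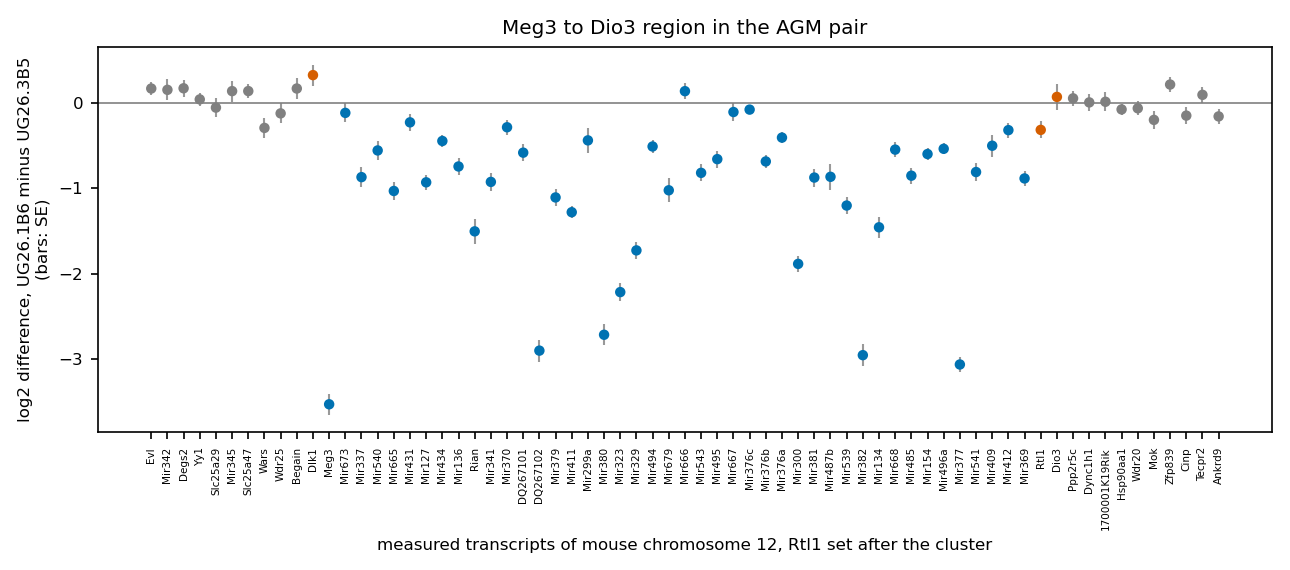
Log2 difference of UG26.1B6 minus UG26.3B5 (vertical axis; bars are standard errors, n = 3 arrays each) for the measured transcripts of the Meg3 to Dio3 region in blue, Dlk1, Rtl1 and Dio3 in orange and 20 flanking genes in grey (horizontal axis, genes in order, with Rtl1 set after the cluster). Meg3 lies at -3.53, 43 of the 44 blue points lie below 0, and the flanking genes have a median of 0.03.

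The FL pair asked the same question for AFT024 against BFC012, lines of 1 strain. AFT024 had higher levels of the imprinted genes Peg10 (5.96), the delta-like surface protein Dlk1 (5.44; 12.90 ± 0.137 against 7.45 ± 0.159, SD, n = 3 each), the amino acid transporter Slc38a4 (5.25) and Sgce (4.74). Butyrylcholinesterase (Bche, 5.30), Hoxc8 (4.99) and Xlr (4.91) were higher too, and Xist, the RNA of the inactive X chromosome, differed by 6.73. BFC012 had higher levels of the uroplakins Upk1b (-5.19) and Upk3b (-4.79), of Tbx20 (-4.86), of P-cadherin (Cdh3, -4.99), the teneurin Tenm3 (-5.93; 5.46 ± 0.153 against 11.39 ± 0.057, SD, n = 3 each), Fndc3c1 (-5.69), the pantetheinase Vnn1 (-5.39) and the adhesion receptor Adgrl2 (-5.33). Standard errors of the 16 differences were 0.083 to 0.248. In all, 5685 genes passed, 3108 higher and 2577 lower in AFT024, and 1048 differed at least 2-fold.

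In the interferon response list 26 of 34 measured genes were higher in AFT024, 0 lower and 8 did not pass (26 and 2 adjusted over the list alone; camera adjusted p = 4.0e-10, adjusted p = 0.389 with an estimated correlation). Rtp4 (3.17), Ifih1 (2.85), Ddx60 (2.79) and Oasl1 (2.78), genes that interferons induce, had the largest differences. Of 18 imprinted growth genes 10 were higher, 3 lower and 5 did not pass (10 and 3 adjusted over the list alone; camera adjusted p = 0.000155, adjusted p = 0.0928 with an estimated correlation). For interstitial collagens 11 of 17 were higher, 1 was lower and 5 did not pass (11 and 2 adjusted over the list alone; camera adjusted p = 0.000155, adjusted p = 0.389 with an estimated correlation). Col6a3 (3.32), Col1a2 (2.91) and Col8a1 (2.38) led this list. YAP and SRF targets, genes of the contractile cytoskeleton and its regulators, went the other way, with 1 higher, 12 lower and 9 not passing among 22 (1 and 12 adjusted over the list alone; camera adjusted p = 0.000192, adjusted p = 0.542 with an estimated correlation). Nt5e (-3.14), Acta2 (-2.83), Myl9 (-2.79) and Tagln (-2.44) were lower in AFT024. The smooth muscle and pericyte markers, which share members with this list, had 4 of 23 higher, 9 lower and 10 not passing (4 and 9 adjusted over the list alone; camera adjusted p = 0.0333, adjusted p = 0.332 with an estimated correlation). Among 39 HSC niche factors 13 were higher, 5 lower and 21 did not pass (14 and 6 adjusted over the list alone; camera adjusted p = 0.134, adjusted p = 0.683 with an estimated correlation). Higher among them were Dlk1, pleiotrophin Ptn (2.35), Angptl4 (1.91) and stem cell factor Kitl (1.60). Camera called 9 lists, 0 of them with an estimated correlation and 3 without the members passing at over 4-fold. Leaving those members out ended the calls of the imprinted genes (adjusted p = 0.580), the collagens (adjusted p = 0.106), the YAP and SRF targets (adjusted p = 0.106) and the smooth muscle markers (adjusted p = 0.385).

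The BM pair set BMC9 against BMC10. BMC9 had higher levels of the transketolase-like Tktl1 (6.00; 11.54 ± 0.232 against 5.54 ± 0.066, SD, n = 3 each), Adgrl2 (5.30), the ribosomal protein variant Rpl39l (4.87), Tmem47 (4.61), the TGF-beta co-receptor endoglin (Eng, 4.46), the natriuretic peptide clearance receptor Npr3 (4.08), Ifi202b (4.01) and the Y-linked Eif2s3y (4.58). BMC10 had higher levels of Bcl6b (-4.87), Nlrp4e (-4.11), the imprinted growth inhibitor Grb10 (-3.77; 5.75 ± 0.364 against 9.52 ± 0.172, SD, n = 3 each), the complement receptor C3ar1 (-3.54), Slc16a13 (-3.52), Arhgdib (-3.37), the transcription factor Sox2 (-3.33) and the protocadherin Pcdh7 (-3.14). Standard errors of the 16 differences were 0.088 to 0.192. In all, 3082 genes passed, 1451 higher and 1631 lower in BMC9, and 473 differed at least 2-fold.

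Of 39 HSC niche factors 10 were higher in BMC9, 2 lower and 27 did not pass (12 and 3 adjusted over the list alone; camera adjusted p = 0.0145, adjusted p = 0.305 with an estimated correlation). The higher ones included pleiotrophin Ptn (3.8), angiopoietin Angpt1 (2.81), the chemokine Cxcl12 that retains stem cells in the marrow (2.58) and Bmp4 (2.01). In the Wnt pathway 15 of 57 were higher, 3 lower and 39 did not pass (15 and 4 adjusted over the list alone; camera adjusted p = 0.00143, adjusted p = 0.305 with an estimated correlation). Sfrp2 (3.67), Rspo2 (1.70), Tcf7l1 (1.57) and Wnt5a (1.48) stood at its top. Interstitial collagens had 8 of 17 higher, 0 lower and 9 not passing (11 and 1 adjusted over the list alone; camera adjusted p = 7.1e-05, adjusted p = 0.305 with an estimated correlation). Osteoblast markers had 6 of 15 higher, 1 lower and 8 not passing (7 and 1 adjusted over the list alone; camera adjusted p = 0.0116, adjusted p = 0.305 with an estimated correlation), among them Dlx5 (1.90), Sp7 (1.13) and Alpl (1.02). The 4 measured sex chromosome genes were the list whose call held with an estimated correlation (camera adjusted p = 1.1e-08, adjusted p = 0.00487 with an estimated correlation). The 3 Y-linked genes were higher in BMC9, Xist (-0.51) was lower, 0 did not pass, and counts adjusted over the list alone were 3 and 1. Xist was weak in both lines, at 4.94 in BMC9 and 5.45 in BMC10, below the first quartile of genes in this set (5.74). Camera called 17 lists, 1 with an estimated correlation and 7 without the members passing at over 4-fold, where the niche factors did not pass (adjusted p = 0.388) and the sex chromosome list could not be tested. With only the 6 arrays of the pair 1296 genes passed, or 2115 with the replicate number as a block (chosen after seeing the data), and with the 18 arrays normalized together 1900.

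The second FL pair, 2012 against AFT011, shares no array with the others. The line 2012 had higher levels of the fibulin Efemp1 (6.41; 12.06 ± 0.036 against 5.6 ± 0.183, SD, n = 3 each), keratinocyte growth factor Fgf7 (5.41) and asporin (Aspn, 4.78). Hoxc8 (4.60), the retinoic acid binding protein Crabp1 (4.49), Slc43a3 (4.44), prostaglandin E synthase Ptges (4.43) and Lipo3 (4.42) were higher too. AFT011 had higher levels of the creatine synthesis enzyme Gatm (-6.94; 5.41 ± 0.243 against 12.36 ± 0.095, SD, n = 3 each), Upk1b (-5.81), Cd34 (-5.08), Tbx20 (-5.0), Ptprz1 (-4.93), Vnn1 (-4.68), the ubiquitin ligase Rnf128 (-4.67) and Serpinb6b (-4.61). Standard errors of the 16 differences were 0.077 to 0.324. In all, 5493 genes passed, 2674 higher and 2819 lower in 2012, and 713 differed at least 2-fold.

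Of 22 YAP and SRF targets 0 were higher in 2012, 12 lower and 10 did not pass (0 and 13 adjusted over the list alone; camera adjusted p = 4.0e-07, adjusted p = 0.264 with an estimated correlation). Tagln (-2.77), Actg2 (-1.75), Cnn1 (-1.66) and Ccn2 (-1.24) had the largest differences. Smooth muscle and pericyte markers had 4 of 23 higher, 11 lower and 8 not passing (4 and 11 adjusted over the list alone; camera adjusted p = 0.00207, adjusted p = 0.103 with an estimated correlation). For the Hox genes 15 of 37 were higher, 7 lower and 15 did not pass (16 and 9 adjusted over the list alone; camera adjusted p = 0.00124, adjusted p = 0.264 with an estimated correlation). Hoxc8, Hoxc6 (4.01), Hoxc12 (3.57) and Hoxc10 (3.19) were the largest. Imprinted growth genes had 8 of 18 higher, 1 lower and 9 not passing (8 and 1 adjusted over the list alone; camera adjusted p = 0.000557, adjusted p = 0.0884 with an estimated correlation). Slc38a4 (4.33), Dlk1 (4.08) and Ndn (3.18) were higher and Peg3 (-3.52) was lower. The epithelial and mesothelial markers had a median of 0.11 but a mean of -0.59 and a camera direction of down (adjusted p = 0.0202, adjusted p = 0.716 with an estimated correlation). Of 19 markers 4 were higher, 6 lower and 9 did not pass (4 and 6 adjusted over the list alone), and the largest were Upk3b (-4.03), Wt1 (-3.16), Lrrn4 (-2.45) and Krt14 (-2.05). Among 39 HSC niche factors 9 were higher, 7 lower and 23 did not pass (11 and 7 adjusted over the list alone; camera adjusted p = 0.406, adjusted p = 0.820 with an estimated correlation). Fgf7, Postn (4.16) and Dlk1 were higher and the Notch ligand Jag1 (-2.54) was lower. In the sex chromosome list 0 of 4 were higher, 3 lower and 1 did not pass (0 and 3 adjusted over the list alone), and this call held with an estimated correlation (camera adjusted p = 8.2e-07, adjusted p = 0.0231 with an estimated correlation). Camera called 12 lists, 1 with an estimated correlation and 2 without the members passing at over 4-fold. Leaving those members out ended the calls of the Hox (adjusted p = 0.392), imprinted (adjusted p = 0.051), smooth muscle (adjusted p = 0.0652) and sex chromosome genes (adjusted p = 0.122), and turned the epithelial and mesothelial markers to up (adjusted p = 0.674).

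Genes past the threshold in 1 direction in the AGM, FL and BM pairs numbered 71, of which 47 were higher in the supportive lines and 24 lower. Independent lists with as many genes per pair and direction, the comparison planned beforehand, would share 18.7 genes. That value leaves out that genes passing in 1 pair may pass more often in another, whatever the direction. In a comparison made after seeing the data, the 71 were 19.5% of the 365 genes past the threshold in all 3 pairs in any direction. Directions unrelated to each other would give 91.2 genes. With the supportive and the other line exchanged in the AGM, FL or BM pair (counts made after seeing the data), 93, 121 or 80 genes went 1 way, so the labels of support gave the lowest count of the 4 arrangements. The extracellular matrix protein Tgfbi was higher by 1.75, 2.21 and 2.47 in the AGM, FL and BM pairs, with a standard error of 0.320 each. The sushi-repeat protein Srpx2 was higher by 1.86, 2.05 and 1.61, and the Wnt modulator Sfrp2 by 1.03, 1.16 and 3.67. Serpinb1a, Sorcs2, Maf, Nynrin, Emb, Cfap20dc and the semaphorin Sema3f were the other 7 named. The receptor Gpr39 was lower by -2.34, -1.66 and -1.72 with a standard error of 0.160, followed by Glipr1, Rnf128, Prex2, Zfp985, Pik3r5, Ica1, Pgap1, Sh3bp5 and Rundc3b. With the mean of its probe sets Zfp985 turned to 0.084 in the FL pair.

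In the second FL pair 20 of the 47 and 14 of the 24 passed in the same direction. The share of all genes would give 6.3 and 3.4. In the opposite direction 11 and 5 passed, Maf (-1.17), Nynrin (-2.21) and Emb (-0.64) among them. Across all genes the differences of the 4 pairs were nearly unrelated. Pearson's r lay between -0.08 and 0.22 over the 6 combinations of pairs, where genes are not independent replicates. Of genes passing in both pairs of a combination, 41.6% to 65.2% went the same way. The shared count was 24 with only the arrays of each pair, 87 with these and the replicate number as a block (chosen after seeing the data), and 20 with the arrays normalized together.

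**Figure D2:**
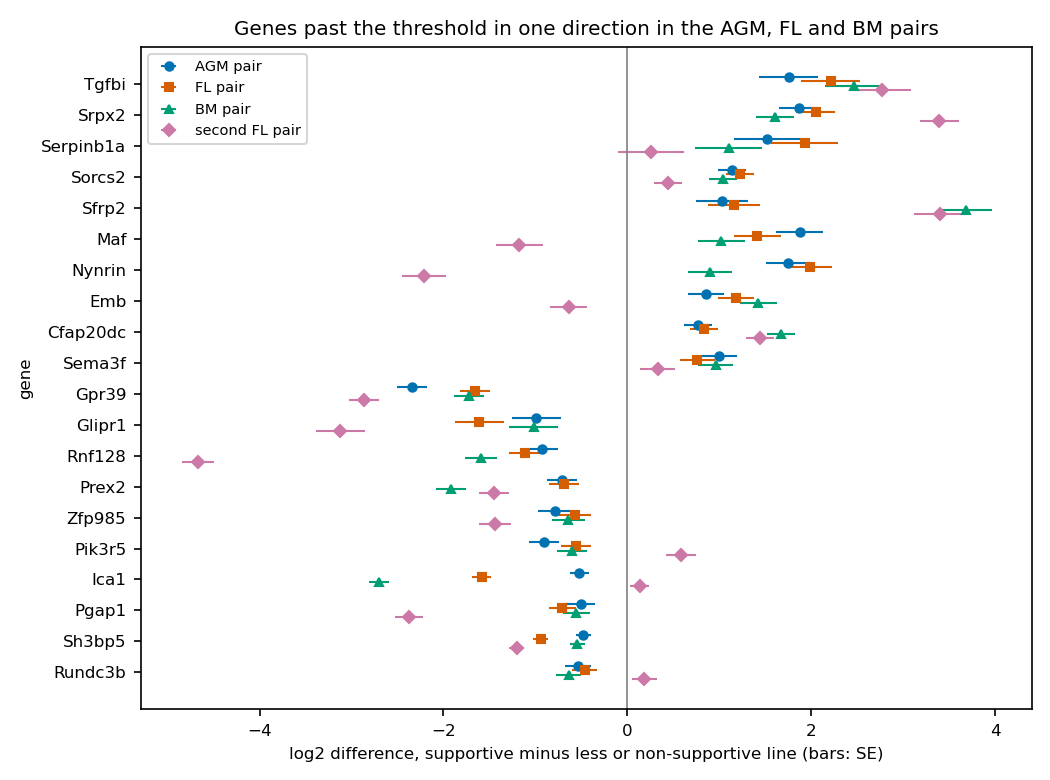
Log2 difference (horizontal axis; supportive minus less or non-supportive line, bars are standard errors, n = 3 arrays each) of the 20 named shared genes (vertical axis) in the AGM, FL, BM and second FL pairs. Tgfbi lies at 1.75 to 2.77 in the 4 pairs and Gpr39 at -1.66 to -2.87, while Maf and Nynrin lie below 0 in the second FL pair.

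Across the 12 lines of 3 tissues, 7 supportive and 5 less or non-supportive, 0 genes passed limma's test for support, and 950 had an unadjusted p under 0.05. The 6 genes with the smallest p, none of which passed, were Gpr39 (-2.15 ± 0.255, SE), Cfap20dc (1.15 ± 0.157), Stxbp2 (-1.10 ± 0.171), Trim65 (-0.41 ± 0.068), Chd1l (-0.41 ± 0.074) and Pbp2 (-0.60 ± 0.111), each with an adjusted p = 0.895. Among the lists, 43 cell cycle genes had a median of -0.11 with 0 passing singly (0 adjusted over the list alone; camera adjusted p = 3.0e-06, adjusted p = 0.642 with an estimated correlation). The 34 interferon response genes had a median of 0.34 with 0 passing singly (0 adjusted over the list alone; camera adjusted p = 0.00022, adjusted p = 0.642 with an estimated correlation). The 22 YAP and SRF targets had a median of -0.20 with 0 passing (0 adjusted over the list alone; camera adjusted p = 0.000528, adjusted p = 0.642 with an estimated correlation). Single pairs went the other way. In the second FL pair 1 interferon gene was higher, 5 lower and 28 did not pass (1 and 5 adjusted over the list alone; camera adjusted p = 0.0653 with direction down, adjusted p = 0.820 with an estimated correlation). In the AGM pair 6 YAP and SRF targets were higher, 0 lower and 16 did not pass (7 and 0 adjusted over the list alone; camera adjusted p = 0.0183, adjusted p = 0.711 with an estimated correlation). For support the fry test called 0 of the 41 lists, where camera called 9. With the arrays of a line as a random block 116 genes passed, and with the FL lines alone, which span 3 normalization sets without a term for them, 8 passed. Trim65 turned to 0.70, Chd1l to 0.50 and Pbp2 to 0.39 with the FL lines alone, and Trim65 to 0.14 without the set term.

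For tissue of origin 14 genes passed limma's F test, each with an adjusted p = 0.0352. BM lines were lower than the mean of the other tissues in Tmem176b (-3.67), the glycosyltransferase B4galt6 (-3.60), the Rac activator Tiam1 (-3.0), Hoxb2 (-2.32), the Wnt co-receptor Lrp5 (-1.44) and Obsl1 (-1.31), and higher in E330013P04Rik (3.35), the matricellular protein Ccn3 (1.81) and the iron-regulating Hfe (0.84). AGM lines were lower in Pcdh19 (-2.03) and Aunip (-0.62), and FL lines were higher in Mpp7 (1.51) and Ankrd55 (0.94) and lower in Pttg1 (-0.92). Strain, age and mode of immortalisation went with tissue and cannot be told apart from it. The supportive BM line 14F1-1 was grown at 37 degrees C while the other lines tested were at 33. The count rested on single lines: without 2012, AFT011, AFT024, BFC012, BMC9, UG26.1B6 or UG26.3B5 it was 0, without BMC10 3 and without AM14-1C4 24, and with no set term 0.

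The FL pair was also compared in sorted cells, from the arrays of AFT024 and BFC012 grown without KLS cells. Xlr (6.59), Xist (6.42), Slc38a4 (5.16), Peg10 (4.76), the glutamate receptor Gria3 (4.74), Brinp3 (4.72), Bche (4.27) and Sgce (4.06) were higher in AFT024. Adgrl2 (-4.81), Tenm3 (-4.35), Gpm6a (-4.04), Tspan8 (-4.01), Upk1b (-3.76), Smarca1 (-3.24), Pde3b (-3.23) and Tbx20 (-3.02) were lower. Standard errors of these 16 differences were 0.124 to 0.920. Gria3 varied widely between the AFT024 arrays (8.62 ± 2.38 against 3.89 ± 0.143 in BFC012, SD, n = 3 each), so the size of its difference is uncertain. In all, 1459 genes passed, 699 higher and 760 lower, and 434 differed at least 2-fold. Of the 5685 genes called in the confluent pair, 1216 (21.4%) passed in the same direction in the sorted pair and 3 in the opposite one, and 87.8% had the same sign. Across all genes the differences of the 2 pairs correlated at Pearson's r = 0.757 and Spearman's rho = 0.579, where genes are not independent replicates.

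The replicate 1 arrays of both sorted groups without KLS cells stood apart from replicates 2 and 3, with 616 genes in AFT024 and 798 in BFC012 over 2-fold away, against 3 and 2 genes between replicates 2 and 3. In AFT024 the 34 interferon response genes lay lower in replicate 1 by a median of -1.47. In the sorted pair this list held 2 genes that passed, Ddx60 (3.71) and Ifih1 (3.24), 0 lower and 32 that did not (22 and 0 adjusted over the list alone; camera adjusted p = 3.1e-11, adjusted p = 0.475 with an estimated correlation). Imprinted growth genes had 6 of 18 higher, 1 lower and 11 not passing (7 and 1 adjusted over the list alone; camera adjusted p = 0.000979, adjusted p = 0.164 with an estimated correlation), with Ndn at -2.51. The 27 adipocyte markers had a median of -0.02, a mean of 0.38 and a camera direction of up (adjusted p = 0.0299, adjusted p = 0.475 with an estimated correlation), with 5 higher, 0 lower and 22 not passing (6 and 0 adjusted over the list alone). Lpl (3.97), Ebf1 (3.64) and Pparg (1.65) were among the 5, and without replicate 1 of AFT024 and BFC012 grown alone and of AFT024 with KLS cells the camera call of the list ended (adjusted p = 0.0955). Without the members passing at over 4-fold it ended too (adjusted p = 0.262), as did that of the imprinted genes (adjusted p = 0.265), and the fry test did not call the interferon list (adjusted p = 0.134) or the adipocyte markers (adjusted p = 0.108). Of 39 HSC niche factors 4 were higher, 2 lower and 33 did not pass (7 and 3 adjusted over the list alone; camera adjusted p = 0.158, adjusted p = 0.624 with an estimated correlation). Dlk1 (2.49), Csf1 (0.84) and Il7 (0.62) were higher and Jag1 (-1.84) was lower.

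With the replicate number as a block and only these 6 arrays, 3152 genes passed in the sorted pair (1598 higher, 1554 lower), 1404 of them also in the fit without it, and with these 6 arrays and no block 884. Without the 3 doubted replicate 1 arrays (AFT024 and BFC012 without KLS cells, AFT024 with KLS cells), an alternative chosen after seeing the data that also lowers the spread, 3901 passed, 1409 of them among the 1459 and in the same direction. Without BFC012 replicate 1 alone the count was 2241, without its replicate 2 or 3 it was 791 or 772, and without AFT024 replicate 2 or 3 it was 779 or 749.

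In the main fit, sorted stroma grown with KLS cells differed from stroma grown alone in both lines. With only the 6 arrays of AFT024, 11 genes passed in that line, and 0 with the replicate number as a block as well. A difference in medium or handling between the cultures was not excluded. In AFT024 the lipid chaperone Fabp4 rose by 2.90 (7.16 ± 0.316 to 10.06 ± 0.302, SD, n = 3 each), followed by the glucocorticoid receptor co-chaperone Fkbp5 (2.85), metallothionein Mt2 (2.82), the acute-phase proteins Orm1 (2.69) and Orm3 (2.5), the aldehyde dehydrogenase Aldh1a7 (2.67), Ctla2a (2.48) and the glutathione synthesis enzyme Gclc (2.08). Lower with KLS cells were the kinase Map2k6 (-1.25), insulin-like growth factor Igf1 (-1.24), Hs6st2 (-1.04), Lbh (-0.97), Tm4sf1 (-0.94), Znhit6 (-0.87), Mex3a (-0.81) and Cklf (-0.70). In BFC012 the acute-phase protein Saa3 rose by 5.2 (6.34 ± 1.41 to 11.54 ± 0.114, SD, n = 3 each), with Mt2 (4.24), lipocalin Lcn2 (4.04), haptoglobin Hp (3.65), the protease inhibitor Timp4 (3.55), the monooxygenase Fmo1 (3.29), Orm3 (3.14) and Fkbp5 (3.12). Pcdh18 (-1.54), Lpar4 (-1.42), Cpa6 (-1.28), Timp3 (-1.21), Igf1 (-1.18), Pcdh19 (-1.08), Hbegf (-1.06) and Rhoj (-1.05) fell. Standard errors were 0.091 to 0.375 for the 16 genes in AFT024 and 0.144 to 0.562 for the 16 in BFC012. In all, 70 genes passed in AFT024, 59 higher and 11 lower, and 176 in BFC012, 122 higher and 54 lower; 39 and 70 of them changed at least 2-fold.

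Both lines shared 20 genes that rose and 4 that fell, and 1 gene, Rhoj, passed in opposite directions. Fkbp5, Mt2, Mt1, Orm1, Per1 and Tsc22d3, genes that glucocorticoids induce, were among the 20, and Igf1, Tm4sf1, Znhit6 and Mex3a were the 4. The replicate 1 arrays grown alone deviated together in the 2 lines (r = 0.671), so the 2 changes are not independent. These arrays met the rule for pairing by replicate number. Yet different numbers correlated at up to 0.501, above the lowest of equal numbers (0.466), so a pairing beyond replicate 1 was not shown. Across all genes the 2 changes correlated at Pearson's r = 0.330 and Spearman's rho = 0.162, where genes are not independent replicates. Without such a pairing in the fit 8 genes passed the interaction test for a response that differed between the lines, and with the replicate number as a block 0 did. In the fit without the pairing Fmo1 (difference of changes -3.07 ± 0.413, SE), Tmem119 (-1.67), Nnmt (-1.39), Tdpoz8 (-1.30), Ap4e1 (-1.10) and Adam10 (-1.0) responded more in BFC012, Dpep1 (1.20) more in AFT024, and the small GTPase Rhoj (2.37 ± 0.247, SE) rose by 1.32 in AFT024 and fell by 1.05 in BFC012.

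**Figure D3:**
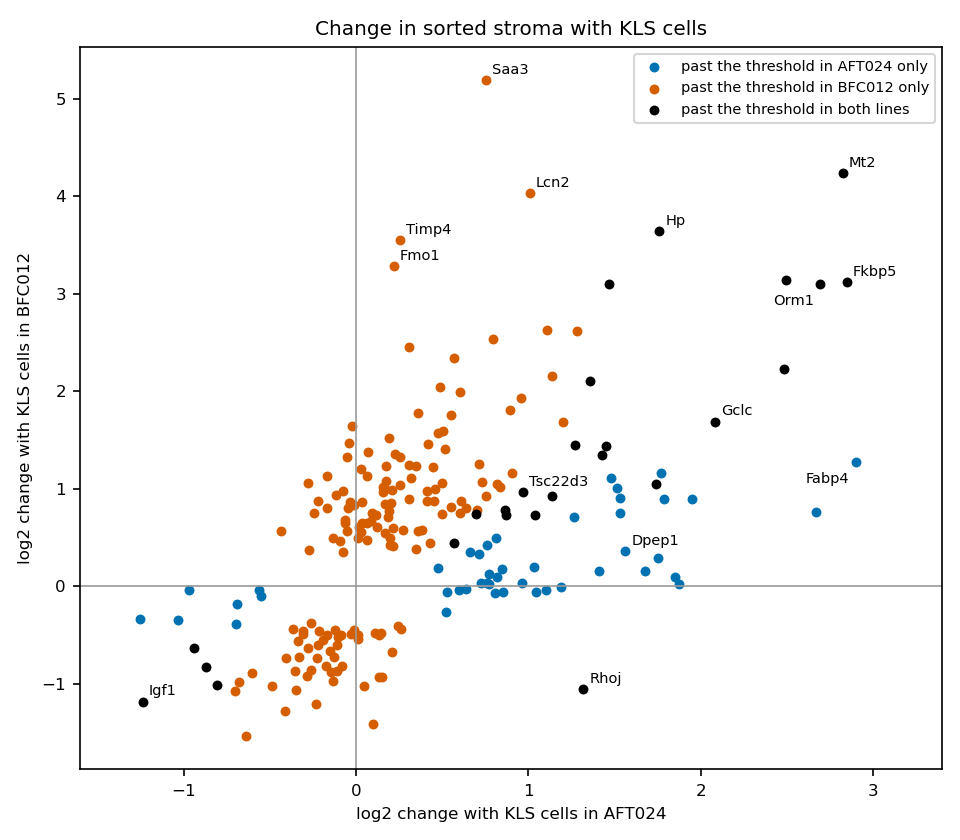
Log2 change with KLS cells in AFT024 (horizontal axis) and BFC012 (vertical axis), n = 3 arrays per group; points are genes past the threshold in AFT024 only, in BFC012 only or in both lines. Mt2 lies at 2.82 and 4.24 and Fkbp5 at 2.85 and 3.12, while Rhoj lies at 1.32 and -1.05.

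Among the niche factors, stem cell factor Kitl rose in BFC012 by 2.62 (7.13 ± 0.791 to 9.7 ± 0.151, SD, n = 3 each), with Prg4 (2.15) and Igfbp2 (1.32), and Igf1 fell. Of the 39 in this list 3 rose, 1 fell and 35 did not pass (3 and 1 adjusted over the list alone; camera adjusted p = 0.662, adjusted p = 0.949 with an estimated correlation). In AFT024 0 of the 39 rose, 1 fell and 38 did not pass (1 and 2 adjusted over the list alone; camera adjusted p = 0.177, adjusted p = 0.863 with an estimated correlation). Kitl stood at 1.28 with an adjusted p = 0.175, and the difference between the lines did not pass (-1.33, adjusted p = 0.528). Oxidative stress genes had 3 risers of 27 in each line, Mt2, Mt1 and Gclc, with 0 fallers and 24 not passing (7 and 0 in AFT024 and 7 and 2 in BFC012 adjusted over the list alone; camera adjusted p = 0.000672 and 0.0111, adjusted p = 0.504 and adjusted p = 0.785 with an estimated correlation). Without the members passing at over 4-fold the call in BFC012 ended (adjusted p = 0.217). Of 28 glycolysis and hypoxia genes 2 rose in AFT024, Ndrg1 (1.75) and Mxi1 (0.80), 0 fell and 26 did not pass (9 and 0 adjusted over the list alone; camera adjusted p = 1.8e-11, adjusted p = 0.507 with an estimated correlation). Of 29 NF-kB and acute inflammation genes 3 rose in BFC012, Saa3, Lcn2 and the NF-kB inhibitor Tnfaip3 (1.32), 0 fell and 26 did not pass (8 and 0 adjusted over the list alone; camera adjusted p = 6.9e-06, adjusted p = 0.656 with an estimated correlation). Cell cycle genes in BFC012 had 1 riser of 43, Mcm6 (0.47), 0 fallers and 42 not passing (2 and 0 adjusted over the list alone; camera adjusted p = 1.5e-11, adjusted p = 0.949 with an estimated correlation). In replicate 1 of BFC012 grown alone this list lay above replicates 2 and 3 by a median of 1.03, which lowers the change with KLS cells. Without the doubted arrays, which also lowers the spread, camera at the preset correlation still called the list up (adjusted p = 3.8e-40). The 29 hematopoietic markers, which KLS cells or some of their progeny would carry, had medians of 0.09 in AFT024 and 0.010 in BFC012. Of these markers 0 passed in either line, and 34 myeloid markers had 0 passing as well. The fry test called 0 of the 41 lists in either line. Limma's tests gave 1845 genes in AFT024 and 2032 in BFC012 at an unadjusted p under 0.05.

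The counts with KLS cells depended on single arrays. In AFT024 the count was 29 and 24 without replicates 2 and 3 grown alone, 149 and 22 without replicates 1 and 2 grown with KLS cells, and 11 with only these 6 arrays. In BFC012 it was 373, 75 and 70 without replicates 1, 2 and 3 grown alone and 85, 77 and 82 without those grown with KLS cells. With the replicate number as a block and only the 6 arrays of a line, chosen after seeing the data, 0 genes passed in AFT024 and 58 in BFC012. Without the 3 doubted arrays 1195 and 2069 genes passed, among them all 70 and all 176 in the same direction, and 758 in the interaction, among them all 8. The interaction count was 0 with the replicate number as a block in the same fit, and 16, 0 and 0 without AFT024 replicates 1, 2 and 3 grown alone, 46, 0 and 1 without those of BFC012, 33, 0 and 2 without those of AFT024 with KLS cells and 0 and 3 without replicates 2 and 3 of BFC012 with KLS cells.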

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

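Chosen only after the result was seen were the tests of a shared difference in handling, of p53 targets and cycling, of hematopoietic carry-over and of the maternal transcripts, and the fit without the doubted arrays. The other tests of this part were written before their results were seen.

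In 8 genes the change with KLS cells differed between AFT024 and BFC012 by limma's test of the difference itself (adjusted p = 0.0217 to adjusted p = 0.0447, n = 3 arrays per group). The changes in AFT024 minus those in BFC012 were -3.07 for Fmo1, -1.67 for Tmem119, -1.39 for Nnmt, -1.30 for Tdpoz8, -1.10 for Ap4e1, -1.0 for Adam10, 1.20 for Dpep1 and 2.37 for Rhoj. Of 100 drawn splits of the arrays within the lines, the real one included, 5 gave at least 8 genes and the highest other gave 15, so chance was not excluded for this count. With the replicate number as a block 0 genes passed, and without the 3 doubted arrays 758. The count was 16, 0 and 0 without AFT024 replicates 1, 2 and 3 grown alone, 46, 0 and 1 without those of BFC012, 33, 0 and 2 without those of AFT024 with KLS cells and 0 and 3 without replicates 2 and 3 of BFC012 with KLS cells.

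The replicate 1 arrays of sorted stroma grown alone stood apart in both lines: 616 genes in AFT024 and 798 in BFC012 lay at least 2-fold from replicates 2 and 3, against 3 and 2 genes between replicates 2 and 3, and replicate 1 with KLS cells lay so from its group in 507 genes in AFT024 and 26 in BFC012. A mixture of the 2 lines was argued against, as the 100 genes most specific to confluent AFT024 were not raised in BFC012 replicate 1 (median -0.023, bootstrap SE 0.033). A difference in culture or handling shared by the 2 arrays may be the source but was not tested apart from the pattern. Their deviations correlated across genes at r = 0.671, against 0.021 for the replicate 1 arrays with KLS cells. This value, known before the test was chosen, shows that the 2 arrays moved alike and does not tell handling from another shared cause. Fewer p53 targets and more cycling may be part of the deviation: the medians of these lists were -1.19 and 0.57 in AFT024 and -0.822 and 1.03 in BFC012, beyond all 10000 random lists of matched expression. The interferon response list moved by -1.47 in AFT024 grown alone and -1.45 with KLS cells and by -0.195 and -0.005 in BFC012, where levels were lower and the difference between the lines was not tested, the labels give no batch, and a biological difference between the cultures stayed open as untested.

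With KLS cells 20 genes rose in both lines, with medians of 1.44 in AFT024 and 1.45 in BFC012, glucocorticoid targets among them. Hematopoietic cells carried past the CD45 sort were argued against only as far as they carry the markers of the list tested. The 29 markers had a median change of 0.092 in AFT024 and 0.010 in BFC012, with 0 passing limma's test. Among them Ptprc changed by 0.10 and 0.04 but decides little. It encodes CD45, the antigen the sort selected against. Its group means of 4.28 to 4.38 lay below the first quartile of genes in this set (4.65). Those of Laptm5 (4.25 to 4.41) and Lcp1 (4.28 to 4.42) did too, so a small carry-over could stay unseen. Cells that lack these markers would not show in them. For these 20 genes the rise did not rest on the doubted arrays alone. Without those arrays all 20 genes were still higher in both lines, with medians of 1.31 and 1.23. The factor by which these were smaller, 1.10 and 1.18 (bootstrap SE 0.064 and 0.083), lay below the 2 set beforehand. But the 20 genes had been chosen for passing with these arrays included, which favours genes whose arrays agree. A small factor was therefore likely, and how far replicate 1 shaped the response of other genes stayed open. Glucocorticoid exposure in the co-culture may be a source but stayed open. It was tested with 15 further targets not looked at singly before. Cebpd, Angptl4, Cdkn1c and Nfkbia among them were also members of lists tested in these contrasts. The 15 had medians of 0.525 in AFT024 and 0.348 in BFC012, above all 10000 random lists of matched expression. Those lists hold genes drawn singly, so genes regulated together can lie beyond them more easily. Without the doubted arrays the medians were 0.251 and 0.129, above 99.9% and 97.4% of the lists, the second short of the share set beforehand. Of the 15 targets 0 passed singly. Whether such a signal came from the KLS cells, the stroma or a difference in medium, which the labels do not give, stayed open, as did other inducers of these genes, and no other biological explanation was tested.

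In the AGM pair 43 of the 44 measured transcripts from Meg3 up to Dio3, Meg3 among them, were lower in UG26.1B6, with a median of -0.83. Loss of a chromosome segment was argued against, because the 20 measured genes around the cluster had a median of 0.028 (bootstrap SE 0.056). A lower output of the maternal transcripts as a unit may be the cause but was not tested apart from the pattern, as the share lower (97.7%) restates it, while of the paternal genes Dlk1 and Dio3 did not pass and Rtl1 was lower (-0.31, adjusted p = 0.0446). Whether that goes back to the imprint, to the regulation of 1 promoter or to a deletion inside the cluster stayed open, as did the difference in support between the 2 lines, which was not tested as a cause.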

How the results depend on the processing

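Chosen after seeing the data were the fit without the doubted arrays, the fit with the arrays normalized together, the replicate block with only the arrays compared, the 4 pair differences as the test of support, and the fit without a set term. For the 419 named results, alternatives gave 6832 values, of which 6034 kept direction and side of the threshold, 790 kept the direction and no longer passed, 3 passed in addition and 5 reversed. The reversed values were Zfp985 in the FL pair with the mean of its probe sets (0.084), and, for support, Trim65 (0.70), Chd1l (0.50) and Pbp2 (0.39) with the FL lines alone and Trim65 (0.14) without the set term. None of the 3 genes passed for support in the first place. The cause of these turns, and of the moves below where none is given, was not tested.

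With only the arrays compared and no block the counts were lower: AGM pair 748, BM pair 1296, sorted pair 884, KLS cells in AFT024 11 and shared genes 24. With the arrays normalized together the AGM pair had 828, the FL pair 4506, the BM pair 1900 and the shared genes 20. The second FL pair rose from 5493 to 7361. Stricter thresholds lowered counts by construction. At least 2-fold were 201 genes in the AGM pair, 1048 in the FL, 473 in the BM, 713 in the second FL and 434 in the sorted pair, 39 and 70 with KLS cells in AFT024 and BFC012, and 7 shared. At an adjusted p under 0.01 the AGM pair had 973, BM 1984, second FL 3620 and sorted pair 561, KLS cells gave 23 in AFT024 and 58 in BFC012, the interaction 0 and the shared genes 28. With the replicate number as a block in the same fit the interaction count was 0, and no other count of a pair or of KLS cells moved by more than 1.5 times. The block with only the arrays compared gave 3152 in the sorted pair, 0 with KLS cells in AFT024 and 58 in BFC012, and 2217 in the AGM, 4085 in the FL, 2115 in the BM and 4404 in the second FL pair and 87 shared genes. The interaction had 5 genes with a trended and robust variance and 0 with all probe sets. Without the 3 doubted arrays, which also lowers the spread, the sorted pair had 3901 genes (1409 of the 1459 kept), KLS cells gave 1195 in AFT024 and 2069 in BFC012 (all 70 and 176 kept) and the interaction 758 (all 8 kept).

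Leaving out 1 array in turn gave 1122 to 1964 genes in the AGM pair, 4987 to 5430 in the FL, 2384 to 2936 in the BM, 3938 to 6164 in the second FL and 749 to 2241 in the sorted pair, 22 to 149 and 70 to 373 with KLS cells in AFT024 and BFC012, 0 to 46 in the interaction and 51 to 92 shared. For support limma gave 0 genes (950 at an unadjusted p under 0.05) and 0 with each line left out. Leaving out 1 line gave 0 to 24 for tissue. The line as a random block gave 116 genes for support and the FL lines alone 8, and every other alternative, the pair differences and the fit without a set term included, gave 0. For tissue the random block gave 2864, no covariate 25, removal of the dimmest genes 25, a trended and robust variance 22, an adjusted p under 0.10 54, a covariate for the later lines in place of the set term 0, AGM against FL lines 0 and no set term 0. The random block treats the arrays of a line as further samples of its tissue. Camera called 91 lists over 9 contrasts, 2 with an estimated correlation. Without the members passing at over 4-fold 63 passed, among them 3 of 9 kept in the FL pair, 7 of 17 in the BM and 2 of 12 in the second FL pair. The fry test called 87 lists: 13 in the AGM, 23 in the FL, 20 in the BM, 25 in the second FL and 6 in the sorted pair and 0 with KLS cells in either line, in the interaction and for support, where camera called 8, 7, 9 and 9. The 15 further glucocorticoid targets fell from medians of 0.525 and 0.348 to 0.251 and 0.129 in AFT024 and BFC012 without the doubted arrays.

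Other limits were of scale and signal. Cyclic loess moved the median of all genes by at most 0.064, in the second FL pair. Replicate numbers did not pair the remaining groups checked: the correlations of equal numbers were 0.065, 0.196 and -0.015 for the FL pair, -0.112, -0.505 and 0.395 for the second FL pair, -0.026, 0.037 and -0.101 for AFT024 and 0.083, 0.069 and 0.135 for BFC012 with and without KLS cells, and 0.021, 0.143 and 0.007 between the lines with KLS cells. The first quartile of the genes lay at 5.74, 4.09, 4.65 and 6.01 in the 4 sets, and no background level was available in the values used here, so how far weak genes stood above it is not known. OP9 was not added to the test of tissue, since it would have been a tissue of 1 line. The interaction compares all sorted groups, so restricting it to the groups compared gives no separate fit.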

Other observations

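The comparison of OP9 with BFC and the choice of the genes named in this part were made only after results had been seen, while the counts of splits were planned. Of the epithelial and mesothelial markers, 2 of 19 were higher, 5 lower and 12 did not pass in the FL pair (2 and 5 adjusted over the list alone; camera adjusted p = 0.0467, adjusted p = 0.734 with an estimated correlation, adjusted p = 0.882 without the members passing at over 4-fold), and 4, 6 and 9 in the second FL pair. With the replicate number as a block the camera call of these markers in the FL pair ended (adjusted p = 0.0511). Of the list, Upk3b (-4.79 and -4.03, supportive minus non-supportive line, FL and second FL pair) and Wt1 (-2.21 and -3.16) were higher in BFC012 and AFT011, and so were Upk1b (-5.19 and -5.81) and Tbx20 (-4.86 and -5.0), which are not in it. In the AGM pair Tbx20 went the other way (2.96). Among lines outside the pairs, Xist stood at 12.29 in AM14-1C4 and 11.87 in AM30-3F4, and in AFT024 at 11.68. The Y-linked Eif2s3y stood at 8.22 in BMC9, 7.80 in AFT011 and 7.29 in OP9 and between 2.63 and 4.09 in the other confluent lines, where levels are not comparable between the 4 normalization sets.

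OP9, supportive, and BFC, non-supportive, were normalized together but differ in tissue, and the labels give 37 degrees C for OP9 replicates 1 and 2 and 33 for its replicate 3 and for BFC. Between them 6857 genes passed, 3488 higher and 3369 lower in OP9. Among the 47 higher genes shared by the AGM, FL and BM pairs, 24 passed in the same direction here and 3 in the opposite one. For the 24 lower genes these counts were 16 and 1. The share of all genes would give 8.2 and 4.1 in the same direction. Sfrp2 (-3.46, OP9 minus BFC) and Glipr1 (1.95) were among those that went the opposite way. Tissue, temperature and support cannot be told apart in this comparison.

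Other splits of the same arrays were counted for each result. For groups of 3 arrays there are 10 splits, too few for a share under 0.05, and the real split was 1 of 10 with as many genes in each pair: AGM 1707 (highest other 227), FL 5685 (126), BM 3082 (436), second FL 5493 (0), sorted 1459 (0), KLS cells in AFT024 70 (2) and in BFC012 176 (0). In the AGM, BM and sorted pairs, where equal numbers met the rule for pairing, the other splits that part all 3 pairs gave at most 2, 2 and 0 genes, and the remaining splits kept the arrays of 2 pairs together. For the shared genes 1 of 100 drawn splits within the pairs, the real one, gave as many as 71 and the highest other gave 2. Mixing arrays of 2 lines leaves few genes in each pair, so these splits do not test whether the directions go with support. For support the real count was 0, which all 100 drawn splits of the 12 lines reach, so they decide nothing, and the highest other gave 14. For tissue 5 of 100 gave at least 14 genes and the highest other gave 96, so chance was not excluded, and a split with 96 genes points to a structure of the lines, which was not tested.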
